A study of Homo sapiens with 12 samples.

How the data were processed

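HK-2 cells, an established human proximal tubule epithelial line, were kept for 72 h in medium alone (control) or in medium with suspended 2,8-dihydroxyadenine (DHA) at 60, 120 or 240 ug/ml. No solvent or carrier of the suspension, and no control with one, is given in the sources used here, so changes against control include any effect one had. Each of the 4 groups held 3 libraries, 12 in all, and groups and replicate numbers were taken from the submitters' sample titles. Per the labels' protocols, total RNA was extracted with TRI Reagent, poly(A) RNA was selected with oligo(dT) beads, fragmented and copied with random primers, the second strand was marked with dUTP, and the libraries were read paired-end on a DNBSEQ instrument. Poly(A) selection favours intact polyadenylated RNA, so short RNAs and RNAs without a tail are measured poorly. Whether the 3 libraries of a group came from separate cultures is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical.

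The deposited table holds 1 value for each of 267165 Ensembl transcripts in each of the 12 libraries, written to 1 decimal. The submitters' processing notes name the build GRCh38.p14. The aligner, the quantification tool, its strand setting and the annotation release are not given in the sources used here. The values are not whole numbers, and the library totals ran from 791808 to 1228979 with a geometric mean of 999925, so the deposited values were treated as a normalized signal, of the kind given by TPM values divided by a size factor per library. This reading rests on the totals, since no source used here names the unit. Per the file headers the columns carry library names alone, and each matched exactly 1 sample. Values of this kind keep no read depth, so the depth of each library is unknown and no counting interval or detection limit could be given. A value of 0 may mean an abundance below the last decimal kept, and 92100 transcripts were listed at 0 in all 12 libraries. No pair of libraries held identical values.

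Transcript identifiers were matched without their version to GENCODE release 29 on GRCh38, and the values of a gene's matched transcripts were summed. This matched 202305 transcripts (75.7%) in 57527 genes, which carried 93.8% to 94.7% of each library's total. The remaining transcripts were not assigned to a gene, and why they had no match was not tested, among them 5106 with a mean above 1. A gene's sum can therefore miss one of its main transcripts, and the level of a gene such as KRT8 may be understated in all groups. Gene symbols came from a table of current symbols where it held the gene (57153 genes) and from the annotation otherwise, and gene positions are those of GENCODE release 29. Genes with a value of at least 1 in at least 3 libraries were kept, leaving 16789 genes, of which 12731 are protein-coding.

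The test planned before the data were examined assumed counts. Because the table holds none, the planned fallback was used, limma-trend on log2(value + 1), with limma 3.58.1 in R 4.3.3. One model with a mean for each of the 4 groups was fitted to the 12 libraries, without covariates. Each dose was compared with control, and 240 with 60 ug/ml, with moderated statistics, and an F statistic tested for any difference among the groups. Adjusted p-values are Benjamini-Hochberg values over the 16789 genes, two-sided, and a gene was called at 0.05. A fold change is on the log2(value + 1) scale, which understates the change of genes with low values. Values are printed as mean ± SD over the 3 libraries of a group. On simulated data for 240 ug/ml against control over 16789 genes, with 50 genes changed at each size, 48% of log2 changes of 0.5, 98% of those of 1, and 100% of those of 2 and of 3 were found, and 9 calls (4.95% of all calls) were false. The changed genes were drawn only from those with a mean level above about 5, so recovery at lower levels was not tested. The list test found the 1 changed list and called 0 others. The simulated noise was drawn independently for each gene. These checks therefore do not show how many genes or lists are called falsely where genes vary together.

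Fixed before the data were examined were 41 gene lists for kidney epithelium, crystal exposure, stress, proliferation, metabolism and other cell types. A list needed 5 tested members, which 37 met. Lists were tested with camera, which asks whether a list's genes rank above or below all other genes, with a preset correlation between genes of 0.01 and adjustment over the 37 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without reference to other genes, were run beside it. For each list the number of members called over all genes is given beside the number adjusted over the list alone. The genes named are those of a rule fixed in advance. It took the 6 highest and 6 lowest log2 fold changes at each dose and the 5 highest and 5 lowest for 240 against 60 ug/ml, among called genes with a mean of at least 1, a symbol that is not a clone or locus name, and no overlap between the libraries of the 2 groups. It added up to 4 members of each list with at least 3 changed members, by adjusted p, and a panel of epithelial, injury and purine genes. In all it named 178 genes, some of which are not reported here, and any other gene named is said to have been chosen after its values were seen. A multi-copy or short RNA (SNORA70), near-identical paralogs (metallothioneins, pregnancy-specific glycoproteins) and an antisense gene (HMGA2-AS1) are uncertain, since reads could have been assigned to a related or overlapping gene.

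Alternatives tried were pseudocounts of 0.1 and 5, scaling each library to an equal total, median-of-ratios factors over genes, no filter on low values, a filter of at least 10 in each library of some group, stricter calling, the replicate number as a block, a fit on only the 2 groups compared, a slope over the doses, and leaving out each library. Added after the data had been seen were protein-coding genes alone, quantile normalization, transcripts in place of genes, and subtraction from each library of the trend of its values with transcript length, with GC content, or with both. Transcript length and GC content of a gene are means over its reference transcripts, weighted by their mean value. Correlations of fold changes with them were computed across 10180 protein-coding genes with a mean of at least 5, which are not independent replicates. Median-of-ratios factors over genes stood in for the planned factors, which need counts, and alternatives that need counts were not run. Expected correlations between doses that share the controls came from 100 simulations of unchanged groups, and expected shared calls from 10. These simulations also drew the noise of each gene independently. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.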

Results

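2,8-dihydroxyadenine (DHA) is a poorly soluble purine that forms crystals in the kidney when adenine phosphoribosyltransferase (APRT) is lacking. The series title asks how it affects the integrity and phenotype of kidney epithelial cells. mRNA was profiled in HK-2 cells, a human proximal tubule line, after 72 h in medium alone (control) or with suspended DHA at 60, 120 or 240 ug/ml, with 3 libraries in each of the 4 groups. Levels are given as mean ± SD of the deposited normalized signal over the 3 libraries of a group (n = 3 throughout), and changes as log2 fold changes with the SE of the limma fit. Read depth is unknown, since the deposited values keep no counts. The totals of the deposited signal were 1228979, 1200782 and 1143851 in control, 1060084, 1052413 and 984049 at 60 ug/ml, 929535, 875886 and 962259 at 120 ug/ml, and 969479, 791808 and 896446 at 240 ug/ml.

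The group means followed the dose along the first principal component, which held 42.4% of the variance (11.3% for the second), while single libraries at 120 and 240 ug/ml overlapped. Its mean score was -43.1 ± 3.99 in control, -9.01 ± 13.1 at 60 ug/ml, 21.1 ± 1.95 at 120 ug/ml and 31.0 ± 8.74 at 240 ug/ml. The third library at 60 ug/ml stood apart from the other two, at 5.56 against -12.6 and -20.0 on this component and 0.116 against -28.5 and -22.4 on the second. On the second component library number 3 was also the highest of its group in control (18.9), at 120 ug/ml (13.8) and at 240 ug/ml (20.2). Across genes, libraries of one group correlated with r from 0.978 to 0.985. Of 16789 genes tested, 7173 (42.7%) differed between any of the 4 groups by limma's F statistic at an adjusted p of 0.05. Because DHA libraries had lower totals, scaling each library to an equal total moved the median log2 fold change of all genes up by 0.16 at 60, 0.30 at 120 and 0.36 at 240 ug/ml, and changes are therefore relative to the deposited scaling.

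**Figure D1:**
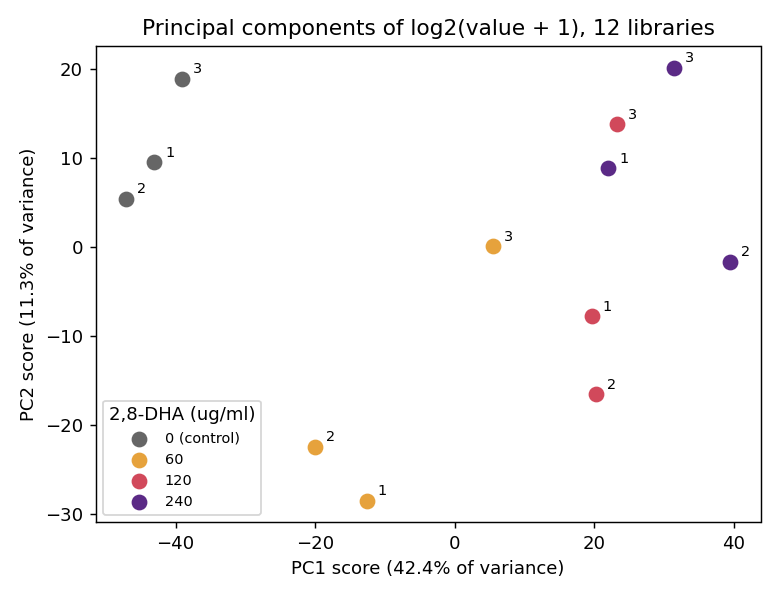
Scores of the 12 libraries on the first (42.4% of variance) and second (11.3%) principal components of log2(value + 1), each point a library and each color a dose. Mean scores on the first component rose from -43.1 in control to 31.0 at 240 ug/ml.

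At 60 ug/ml, CCND1, which encodes the G1 cyclin D1 (ENSG00000110092.3, chromosome 11, 69641087 to 69654474, plus strand of GRCh38), rose from 5.63 ± 1.16 to 28.4 ± 7.30, a log2 fold change of 2.13 (SE 0.18, limma adjusted p = 1.24e-04). CSF2, the growth factor GM-CSF, rose from 8.67 ± 2.30 to 38.2 ± 10.7, and SLC7A5, a transporter of large neutral amino acids, from 22.3 ± 4.403 to 85.1 ± 30.9. SCEL, a cornified envelope protein, and SLCO4A1, an organic anion transporter, rose by 1.94 and 1.82, and the short multi-copy SNORA70, whose assignment is uncertain, by 2.06. MMP7, the metalloproteinase matrilysin (ENSG00000137673.8, chromosome 11, 102520508 to 102530753, minus strand), fell from 382 ± 71.3 to 104 ± 48.3 (-1.95, SE 0.33, limma adjusted p = 0.00284). The interferon-induced genes UBD (-2.21) and GBP2 (-1.59), the BMP target ID3 (-1.57), ATOH8 (-1.56) and PLCXD2 (-1.57) also fell.

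In total 1492 genes were higher and 1685 lower at 60 ug/ml than in control, 84 and 138 of them by a log2 fold change of 1 or more. With equal library totals the split became 2782 higher and 657 lower. Leaving out control replicate 1 gave 920 higher and 968 lower, leaving out the first library at 60 ug/ml gave 922 and 1013, and leaving out control replicate 2 gave 1071 lower. Without the third library at 60 ug/ml, which stood apart, they were 1201 and 1306. Fold changes correlated across genes with GC content (r = 0.39) and transcript length (r = 0.23), and the GC correlation of the 3 libraries at 60 ug/ml was 0.70, 0.50 and 0.20. With each library's GC trend subtracted, 65.5% of the calls at 60 ug/ml kept their direction and their side of the threshold. The share was 90.9% with the length trend and 61.2% with both trends subtracted.

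Of the 37 lists tested, camera called 12 at 60 ug/ml, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 15. Among immediate early genes, induced within minutes to hours by growth factors, 18 of 26 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 1.13e-13, adjusted p = 0.114 with an estimated correlation). Hypoxia and glycolysis genes rose in 9 of 33 cases (9 adjusted over the list alone, median 0.26, camera adjusted p = 3.32e-04, adjusted p = 0.641 with an estimated correlation). In the S phase list 12 of 38 rose (16 adjusted over the list alone, median 0.25, camera adjusted p = 2.63e-05, adjusted p = 0.635 with an estimated correlation). The unfolded protein and integrated stress list had 9 of 34 higher and 2 lower, the same numbers adjusted over the list alone (median 0.10, camera adjusted p = 0.0104, adjusted p = 0.635 with an estimated correlation).

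Of 48 cytosolic ribosomal protein mRNAs, 29 fell at 60 ug/ml (33 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 6.09e-13, adjusted p = 0.635 with an estimated correlation). Among nuclear genes of the respiratory chain 15 of 44 fell and 3 rose (19 and 3 adjusted over the list alone, median -0.32, camera adjusted p = 2.78e-04, adjusted p = 0.688 with an estimated correlation). Mesenchymal markers fell in 10 of 21 cases and rose in 1 (12 and 1 adjusted over the list alone, median -0.36, camera adjusted p = 2.78e-04, adjusted p = 0.148 with an estimated correlation). SPARC, a matrix-binding glycoprotein, fell from 1963 ± 150 to 794 ± 151. Collagens and other matrix genes had 9 of 24 lower and 1 higher (10 and 1 adjusted over the list alone, median -0.33, camera adjusted p = 0.0104, adjusted p = 0.635 with an estimated correlation). Inflammasome and complement genes had 6 of 15 lower (7 adjusted over the list alone, median -0.43, camera adjusted p = 0.0015, adjusted p = 0.148 with an estimated correlation).

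The autophagy list had 10 of 26 members lower at 60 ug/ml (13 adjusted over the list alone, median -0.24, camera adjusted p = 0.00131, adjusted p = 0.114 with an estimated correlation), among them GABARAP, an ATG8-family protein of autophagosomes, which fell from 510 ± 38.6 to 296 ± 29.5. In the primary cilium list 8 of 31 fell and 2 rose (10 and 2 adjusted over the list alone, median -0.22, camera adjusted p = 0.0103, adjusted p = 0.114 with an estimated correlation). IFT52 and IFT20, components of intraflagellar transport, fell by 0.80 and 0.83, while CEP164 of the centriole appendages rose by 0.44. Cholesterol synthesis genes had 3 of 25 lower (9 adjusted over the list alone, median -0.25, camera adjusted p = 0.00939, adjusted p = 0.635 with an estimated correlation). Over all 37 lists tested, which are not independent, the medians of the 3 treated libraries all lay on one side of those of the 3 controls in 15, where chance gives 10%. Of the lists called, hypoxia and glycolysis and the S phase list overlapped the controls.

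At 120 ug/ml the genes that led at 60 ug/ml lay further from control. CCND1 reached 56.8 ± 5.72 (log2 fold change 3.13, SE 0.18, limma adjusted p = 4.86e-06), CSF2 57.5 ± 4.79 and SLC7A5 146 ± 2.60, beside SCEL (2.66) and the uncertain SNORA70 (3.04). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 16.5 ± 2.06 to 134 ± 18.8 (2.94). MMP7 fell to 28.5 ± 2.32 (-3.68, SE 0.33, limma adjusted p = 2.84e-05). CFI, a protease of the complement system, fell from 8.77 ± 2.31 to 0.3 ± 0.173 (-2.89). The monocyte chemokine CCL2 (-2.47), the phospholipase PLA1A (-2.58) and angiotensinogen AGT (-2.42) also fell.

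In total 2670 genes were higher and 3485 lower at 120 ug/ml than in control, 237 and 659 of them by a log2 fold change of 1 or more. With equal library totals the split was 6090 higher and 1378 lower. Fold changes correlated with transcript length across genes (r = 0.34) and little with GC content (r = 0.05). With the length trend subtracted 83.7% of the calls at 120 ug/ml were kept, and 92.1% with the GC trend subtracted.

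Camera called 17 lists at 120 ug/ml, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 27. Over all 37 lists tested, the medians of the treated libraries lay on one side of the controls in 26, where chance gives 10%. Immediate early genes had 20 of 26 higher and 3 lower (20 and 4 adjusted over the list alone, median 0.87, camera adjusted p = 2.80e-09, adjusted p = 0.196 with an estimated correlation). Hypoxia and glycolysis genes had 16 of 33 higher (18 adjusted over the list alone, median 0.45, camera adjusted p = 1.97e-06, adjusted p = 0.469 with an estimated correlation). In the S phase list 15 of 38 rose (15 adjusted over the list alone, median 0.29, camera adjusted p = 3.16e-05, adjusted p = 0.493 with an estimated correlation), and in the mitosis list 18 of 36 rose and 1 fell (22 and 2 adjusted over the list alone, median 0.41, camera adjusted p = 2.88e-05, adjusted p = 0.513 with an estimated correlation). The stress list had 13 of 34 higher (13 adjusted over the list alone, median 0.17, camera adjusted p = 5.20e-04, adjusted p = 0.443 with an estimated correlation). Ion transport genes had 10 of 23 higher and 4 lower (12 and 4 adjusted over the list alone, median 0.25, camera adjusted p = 0.0414, adjusted p = 0.237 with an estimated correlation).

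All 48 ribosomal protein mRNAs fell at 120 ug/ml (48 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 6.08e-15, adjusted p = 0.462 with an estimated correlation). Respiratory chain genes had 26 of 44 lower and 1 higher (32 and 1 adjusted over the list alone, median -0.57, camera adjusted p = 1.49e-06, adjusted p = 0.496 with an estimated correlation). Both groups consist mostly of short mRNA, and the shortest decile of protein-coding genes had a median of -0.46. Mesenchymal markers had 13 of 21 lower and 1 higher (15 and 2 adjusted over the list alone, median -0.68, camera adjusted p = 1.74e-04, adjusted p = 0.196 with an estimated correlation), and matrix genes 14 of 24 lower and 1 higher (14 and 1 adjusted over the list alone, median -0.44, camera adjusted p = 1.48e-04, adjusted p = 0.324 with an estimated correlation). Inflammasome and complement genes had 10 of 15 lower (11 adjusted over the list alone, median -0.81, camera adjusted p = 1.74e-04, adjusted p = 0.196 with an estimated correlation). Proximal tubule genes had 7 of 16 lower and 2 higher (8 and 2 adjusted over the list alone, median -0.47, camera adjusted p = 0.0485, adjusted p = 0.532 with an estimated correlation), and replication-dependent histones 5 of 9 lower (5 adjusted over the list alone, median -0.63, camera adjusted p = 0.0414, adjusted p = 0.462 with an estimated correlation).

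For 4 of the lists called at 120 ug/ml the sign of the median changed with equal library totals, which moved the median of all genes to 0.27, and these lists still lay below it. The lysosome list had 21 of 37 lower and 3 higher (24 and 3 adjusted over the list alone) and a median of -0.34, which was 0.02 with equal library totals (camera adjusted p = 0.00101, adjusted p = 0.462 with an estimated correlation). Cholesterol synthesis had 11 of 25 lower (16 adjusted over the list alone) and a median of -0.32, or 0.02 with equal totals (camera adjusted p = 0.0025, adjusted p = 0.462 with an estimated correlation). Autophagy had 11 of 26 lower and 3 higher (12 and 3 adjusted over the list alone) and a median of -0.24, or 0.12 with equal totals (camera adjusted p = 0.00891, adjusted p = 0.196 with an estimated correlation). The interferon response had 12 of 29 lower and 2 higher, the same numbers adjusted over the list alone, and a median of -0.32, or 0.01 with equal totals (camera adjusted p = 0.0414, adjusted p = 0.414 with an estimated correlation).

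At 240 ug/ml, the highest dose, CCND1 stood at 66.6 ± 5.14, a fold of 10.3 over control on the value + 1 scale of the fit (log2 fold change 3.36, SE 0.18, limma adjusted p = 3.23e-06). SLCO4A1 rose from 41.9 ± 6.44 to 298 ± 35.0 (2.81), ANGPTL4 to 154 ± 3.04 (3.15), SLC7A5 to 154 ± 9.44 (2.75) and TMEM158, a gene induced by Ras signalling, from 1 ± 0.1 to 12.3 ± 2.01 (2.73), beside the uncertain SNORA70 (3.18). MMP7 fell to 17.8 ± 7.27 (-4.42, SE 0.33, limma adjusted p = 8.16e-06). CFI fell to 0.367 ± 0.0577 (-2.81) and PLA1A from 55.1 ± 7.59 to 5.63 ± 0.289 (-3.07). The interferon-induced membrane protein IFITM1 (-3.06) and NKAIN4 (-2.82), a partner of the sodium pump, were also among the lowest.

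In total 3306 genes were higher and 3938 lower at 240 ug/ml than in control, 352 and 871 of them by a log2 fold change of 1 or more. With equal library totals the split was 7205 higher and 1531 lower. Among protein-coding genes 2942 were higher and 3431 lower of 12731 tested. Camera called 18 of the 37 lists, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and fry called 28. Over all 37 lists the medians of the treated libraries lay on one side of the controls in 28, where chance gives 10%. Of the lists called, the S phase list overlapped the controls.

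Immediate early genes stood highest among the lists at 240 ug/ml, with 20 of 26 higher and 4 lower (20 and 5 adjusted over the list alone) and a median of 1.01 (camera adjusted p = 2.40e-08, adjusted p = 0.276 with an estimated correlation). The phosphatases DUSP5 and DUSP6, which switch off MAP kinases, rose from 18 ± 3.45 to 110 ± 15.9 (2.56, SE 0.15) and from 7.97 ± 1.19 to 50.3 ± 4.97 (2.52, SE 0.12). FOSL1, an AP-1 transcription factor (ENSG00000175592.8, chromosome 11, 65892049 to 65900573, minus strand), rose from 28.4 ± 1.59 to 131 ± 11.1 (2.16), and PHLDA1 rose by 2.03.

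**Figure D2:**
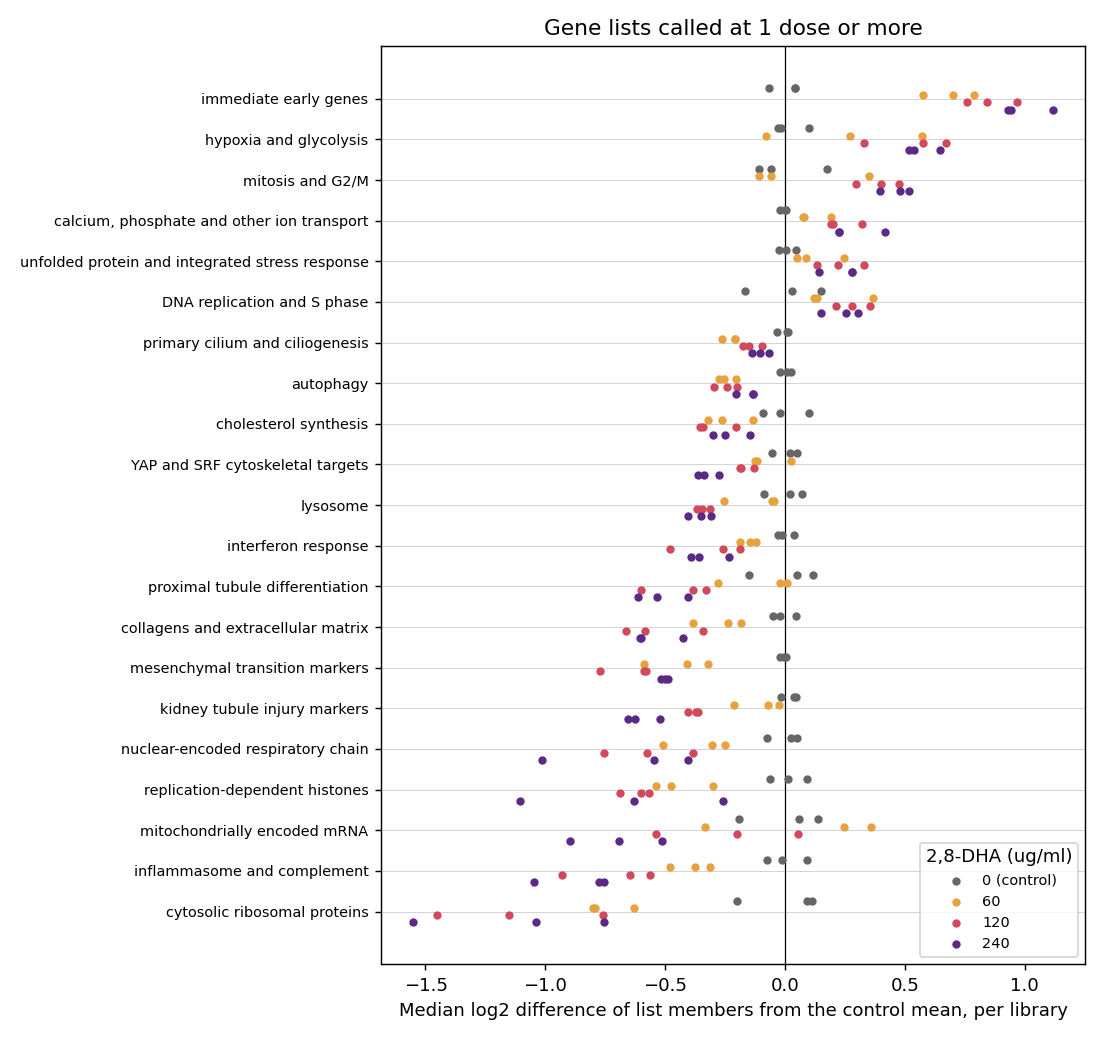
Median log2 difference from the control mean for the 21 lists called at 1 or more doses, each point a library and each color a dose. Ribosomal protein mRNA had a median fold change of -1.12 and immediate early genes of 1.01 at 240 ug/ml. With equal library totals the medians of the lysosome, cholesterol, YAP and SRF, autophagy and cilium lists at 240 ug/ml turned positive but stayed below the median of all genes (0.33), and that of mitochondrial mRNA was 0.01 after quantile normalization.

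All 48 cytosolic ribosomal protein mRNAs fell at 240 ug/ml (48 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 6.65e-14, adjusted p = 0.483 with an estimated correlation). RPS23 went from 2899 ± 123 to 906 ± 276 (-1.73) and RPS20 from 4305 ± 425 to 1250.0 ± 378 (-1.83). The share of ribosomal protein mRNA in a library's total was 16.5%, 17.3% and 14.4% in control and 11.03%, 7.63% and 9.52% at 240 ug/ml. Nuclear genes of the respiratory chain had 28 of 44 lower (29 adjusted over the list alone, median -0.64, camera adjusted p = 2.17e-06, adjusted p = 0.499 with an estimated correlation). The shortest decile of protein-coding genes, of any function, was close to this list, with a median of -0.55 and 60.7% lower. COX6A1 of cytochrome c oxidase fell from 949 ± 22.65 to 402 ± 104 (-1.27). The mitochondrially encoded mRNAs had 6 of 13 lower (7 adjusted over the list alone) and a median of -0.69, or 0.01 after quantile normalization (camera adjusted p = 0.00818, adjusted p = 0.555 with an estimated correlation). MT-CO3 went from 23761 ± 1961 to 8442 ± 1643 (-1.51). After quantile normalization 27 ribosomal protein mRNAs fell and 2 rose, with a median of -0.40.

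Across 10180 protein-coding genes the fold change at 240 ug/ml correlated with length at r = 0.38 and with GC content at r = -0.10. The median fold change ran from -0.55 in the shortest decile of genes (median length 848 nt) to 0.25 in the longest (6102 nt). In the shortest decile 60.7% of genes were lower and 4.22% higher, and in the longest 13.8% were lower and 47.6% higher. Of all calls at 240 ug/ml, 80.5% were kept with the length trend subtracted and 90.5% with the GC trend subtracted.

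**Figure D3:**
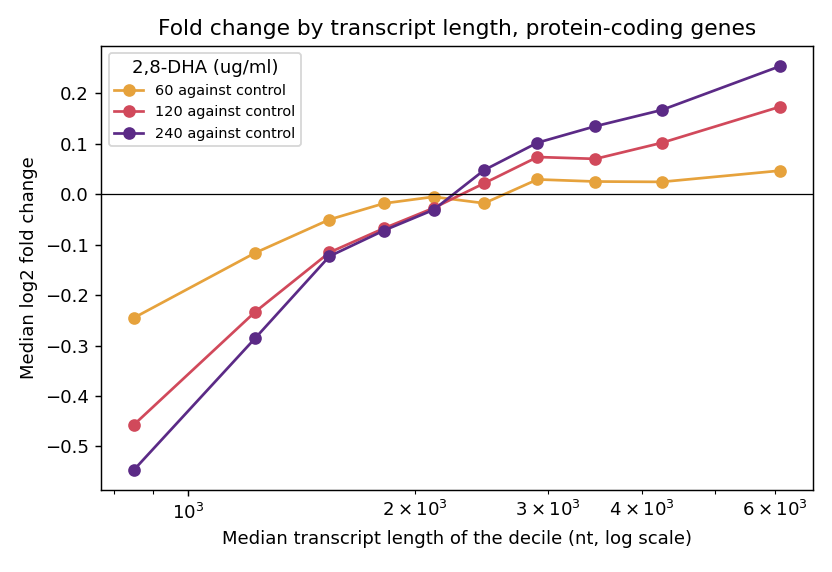
Median log2 fold change against control for 10180 protein-coding genes in deciles of transcript length (nt, log axis), with a line for each dose. At 240 ug/ml the medians ran from -0.55 for the shortest to 0.25 for the longest genes.

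Genes of hypoxia and glycolysis rose in 19 of 33 cases at 240 ug/ml (21 adjusted over the list alone) with a median of 0.53 (camera adjusted p = 4.72e-06, adjusted p = 0.498 with an estimated correlation). VEGFA, the vascular growth factor, rose from 40.8 ± 6.99 to 192 ± 32.9 (2.21), HK2, the first enzyme of glycolysis, from 15.4 ± 1.82 to 55.5 ± 1.19 (1.79), and the carbonic anhydrase CA12 by 1.78. The unfolded protein and integrated stress list had 15 of 34 higher and 2 lower, the same numbers adjusted over the list alone (median 0.28, camera adjusted p = 7.79e-04, adjusted p = 0.433 with an estimated correlation). Its leading members ASNS (1.44), PSAT1 (1.14) and CTH (1.24) make the amino acids asparagine, serine and cysteine, and EDEM1 (0.86) acts in the disposal of misfolded proteins. The NRF2 list was not called, with 8 of 24 higher and 8 lower, the same numbers adjusted over the list alone (median -0.12, or 0.31 with equal totals, mean 0.02, tested upward, camera adjusted p = 0.818). Within it HMOX1, which degrades heme (ENSG00000100292.16, chromosome 22, 35380361 to 35394214, plus strand), rose from 36.9 ± 3.20 to 99.3 ± 13.96 (1.40, SE 0.17, limma adjusted p = 8.05e-05) and the thioredoxin reductase TXNRD1 by 1.51, while AKR1C3, an aldo-keto reductase, fell by 2.35. Heat shock genes had 9 of 20 higher and 5 lower (10 and 5 adjusted over the list alone, median 0.25, camera adjusted p = 0.497), with the co-chaperone BAG3 higher (0.63) and the small heat shock proteins HSPB8 (-1.71), CRYAB (-1.39) and HSPB1 (-1.03) lower. Metallothionein and metal response genes had 3 of 11 higher and 4 lower, the same numbers adjusted over the list alone (median 0.21, mean -0.31, tested upward, camera adjusted p = 0.998), MT1F falling from 366 ± 25.1 to 58.3 ± 26.2, with its near-identical copies uncertain.

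The mitosis list had 23 of 36 higher and 4 lower at 240 ug/ml (26 and 4 adjusted over the list alone, median 0.48, camera adjusted p = 1.03e-04, adjusted p = 0.535 with an estimated correlation). MKI67, a marker of cycling cells, rose from 33.4 ± 6.52 to 72.9 ± 4.45 (1.12, SE 0.18, limma adjusted p = 4.38e-04), and the mitotic kinases PLK1 and AURKB rose by 0.87 and 0.79. In the S phase list 15 of 38 rose (13 adjusted over the list alone, median 0.25, camera adjusted p = 4.20e-04, adjusted p = 0.534 with an estimated correlation), including E2F1 (0.59) and POLE (0.51). Replication-dependent histones, whose mRNA mostly lacks a poly(A) tail, had 4 of 9 lower (6 adjusted over the list alone, median -0.68, camera adjusted p = 0.0175, adjusted p = 0.446 with an estimated correlation). The p53 list had 8 of 27 higher and 11 lower, the same numbers adjusted over the list alone (median -0.13, or 0.30 with equal totals, camera adjusted p = 0.901). CDKN1A, its cell cycle inhibitor, went from 78.2 ± 5.88 to 64.9 ± 6.73 (-0.27, limma adjusted p = 0.0415), and to 0.16 with equal totals. Apoptosis and ferroptosis genes had 5 of 25 higher and 7 lower (5 and 8 adjusted over the list alone, median -0.10, or 0.31 with equal totals, camera adjusted p = 0.662), with CHAC1, which degrades glutathione, higher (2.00) and the survival factor BCL2 lower (-1.19).

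At 240 ug/ml, mesenchymal markers had 13 of 21 lower and 1 higher (14 and 1 adjusted over the list alone, median -0.61, camera adjusted p = 4.20e-04, adjusted p = 0.276 with an estimated correlation). SPARC (ENSG00000113140.10, chromosome 5, 151661096 to 151687165, minus strand) fell from 1963 ± 150 to 329 ± 67.7 (-2.59, SE 0.17, limma adjusted p = 4.75e-06), and TGFBI, an adhesion protein induced by TGF-beta, from 1452 ± 183 to 378.5 ± 101. The mesenchymal genes VIM (1542 ± 47.3 to 1624 ± 74.9, 0.07), FN1 (7318 ± 960 to 6677 ± 420, -0.13) and CDH2 (71.5 ± 2.86 to 66.6 ± 2.62, -0.10) did not pass, with limma adjusted p of 0.619, 0.596 and 0.426. Scaling changed this, since CDH2 passed as higher with equal totals (0.32, limma adjusted p = 0.0334), FN1 after quantile normalization (0.38, limma adjusted p = 0.045), and VIM with both (0.51 and 0.84, limma adjusted p = 0.00168 and 1.81e-04). Collagens and other matrix genes had 14 of 24 lower and 1 higher (14 and 1 adjusted over the list alone, median -0.55, camera adjusted p = 1.68e-04, adjusted p = 0.386 with an estimated correlation). COL4A1, a basement membrane collagen, fell from 628 ± 31.1 to 204 ± 24.4 (-1.62) and COL1A1 from 17.5 ± 1.91 to 4.70 ± 0.400 (-1.70). The YAP and SRF list had 15 of 28 lower and 4 higher (15 and 5 adjusted over the list alone) and a median of -0.31, or 0.11 with equal totals (camera adjusted p = 0.0149, adjusted p = 0.483 with an estimated correlation), with the myosin light chain MYL9 (-1.46) and the matricellular CCN2 (-1.43) lower. TGF-beta response genes had 5 of 21 higher and 8 lower, the same numbers adjusted over the list alone (median -0.13, or 0.28 with equal totals, camera adjusted p = 0.363), with ID1 (-1.83) and the ligand TGFB2 (-1.15) lower.

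Tight junction genes, which bear on the integrity in the series title, moved both ways at 240 ug/ml. Of 25 of them 4 rose and 6 fell, the same numbers adjusted over the list alone (median -0.0048, or 0.35 with equal totals, camera adjusted p = 0.903, fry adjusted p = 0.209). CLDN1, a sealing claudin (ENSG00000163347.5, chromosome 3, 190305701 to 190322475, minus strand), rose from 207 ± 11.2 to 344 ± 12.6 (0.73, SE 0.09, limma adjusted p = 7.29e-05). The polarity protein CRB3 (-0.99), the junctional adhesion molecule F11R (-0.74) and CGNL1 (-0.87) fell. TJP1, the scaffold ZO-1, was 16.3 ± 2.46 in control and 18.3 ± 2.43 at 240 ug/ml (0.16, limma adjusted p = 0.321), and occludin OCLN was 1.07 ± 0.379 and 1.13 ± 0.0577 (0.06, limma adjusted p = 0.816). CLDN2, a cation-pore claudin of the proximal tubule, measured 146 ± 40.2, 226 ± 59.9, 133 ± 35.2 and 93.7 ± 16.2 over the 4 groups in order of dose, none of which passed against control (limma adjusted p of 0.12, 0.745 and 0.0873). Of 21 adherens junction, desmosome and epithelial identity genes 9 fell and 4 rose (9 and 5 adjusted over the list alone, median -0.12, or 0.17 with equal totals, camera adjusted p = 0.242). Fry, without reference to other genes, called this list lower (fry adjusted p = 1.79e-04), and the medians of the 3 treated libraries lay below those of the 3 controls. Plakoglobin JUP fell from 84.1 ± 4.06 to 39.5 ± 4.37 (-1.08), EPCAM from 236 ± 5.96 to 161 ± 14.98 (-0.55) and the kidney cadherin CDH16 by 1.85, while E-cadherin CDH1, low throughout, went from 1.87 ± 0.737 to 0.233 ± 0.0577 (-1.19, limma adjusted p = 0.00389).

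Integrin and hemidesmosome genes had 8 of 26 higher and 8 lower, the same numbers adjusted over the list alone (median -0.08, or 0.34 with equal totals, camera adjusted p = 0.998). The laminin chain LAMB3 rose by 1.26 and the cytolinker PLEC by 1.00, and the epithelial integrin ITGB6 fell by 1.31. Of 6 keratins 1 rose and 3 fell (2 and 3 adjusted over the list alone, median -0.28, or 0.15 with equal totals, camera adjusted p = 0.743). KRT18 was 145 ± 10.8 in control and 155 ± 17.4 at 240 ug/ml (0.09, limma adjusted p = 0.514), and KRT8, whose sum may lack a main transcript, fell by 1.05.

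**Figure D4:**
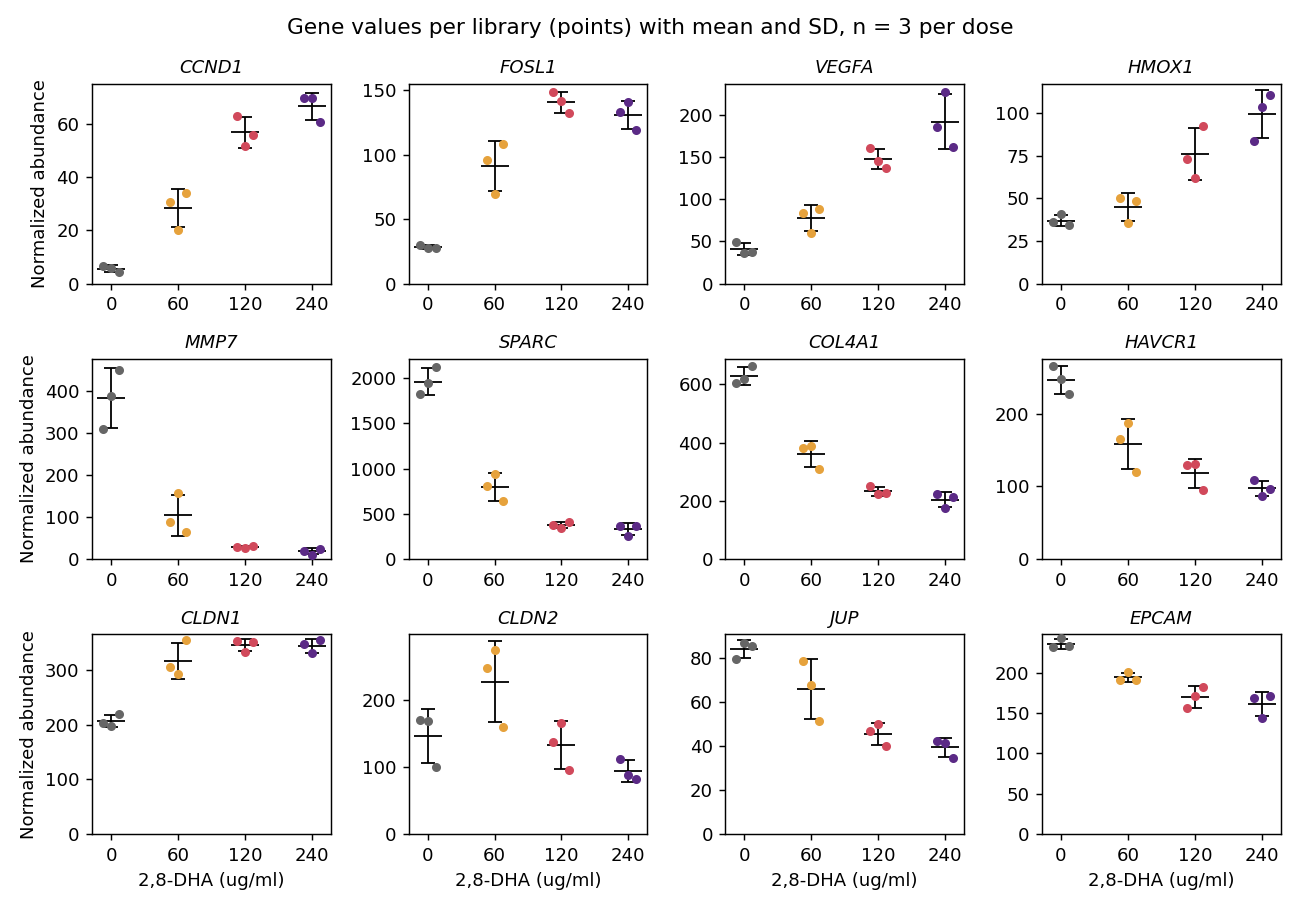
Deposited signal of 12 genes at each dose, with points for libraries and bars for mean and SD (n = 3). CCND1 rose from a mean of 5.63 in control to 66.6 at 240 ug/ml, MMP7 fell from 382 to 17.8, and CLDN2 was highest at 60 ug/ml (226).

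Kidney injury markers moved apart. In that list 12 of 22 fell and 5 rose (14 and 5 adjusted over the list alone, median -0.64, camera adjusted p = 0.0221, adjusted p = 0.422 with an estimated correlation). HAVCR1, the injury marker KIM-1 (ENSG00000113249.12, chromosome 5, 157029413 to 157059119, minus strand), fell from 247 ± 19.5 to 97.2 ± 10.9 (-1.34, SE 0.17, limma adjusted p = 1.05e-04). IGFBP7 fell by 1.64, while the transcription factors SOX9, active in tubule repair, and KLF4 rose by 2.04 and 1.38. LCN2, the marker NGAL, was 6.63 ± 1.55 and 3.60 ± 1.54 (-0.76, limma adjusted p = 0.0598). Proximal tubule genes had 8 of 16 lower and 1 higher, the same numbers adjusted over the list alone (median -0.54, camera adjusted p = 0.0134, adjusted p = 0.498 with an estimated correlation), among them the glucose transporter SLC2A2 (-1.63) and the bicarbonate transporter SLC4A4 (-0.87).

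At 240 ug/ml, inflammasome and complement genes had 10 of 15 lower (10 adjusted over the list alone, median -0.90, camera adjusted p = 3.02e-04, adjusted p = 0.276 with an estimated correlation), with C1S (-1.49) and C1R (-1.11) beside CFI. The interferon list had 5 of 29 higher and 13 lower (5 and 14 adjusted over the list alone, median -0.34, camera adjusted p = 0.0515). The NF-kB list had 9 of 25 higher and 8 lower, the same numbers adjusted over the list alone (median 0.09, camera adjusted p = 0.363). Its chemokine CXCL2 rose by 1.32 and CSF2 by 2.70, while IL11 fell by 1.43 and the chemokine CCL2 of the panel fell from 12.7 ± 7.50 to 1.03 ± 0.603. CXCL8 was 194 ± 33.4 and 288 ± 39.2 (0.57, limma adjusted p = 0.0918).

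Genes tied to purines and crystals gave mixed values. The purine list had 14 of 30 higher and 6 lower, the same numbers adjusted over the list alone (median 0.35, camera adjusted p = 0.0512), with the ecto-nucleotidase NT5E rising from 6.77 ± 2.04 to 32.1 ± 1.72 (2.12), the purine base transporter SLC43A3 by 0.81, and IMPDH1 of guanine nucleotide synthesis by 0.72. APRT itself was 125 ± 7.65 in control and 114 ± 9.18 at 240 ug/ml (-0.13, SE 0.10, limma adjusted p = 0.334), and passed as higher with equal totals (0.30, limma adjusted p = 0.0118). XDH, the enzyme that makes DHA from adenine, went from 0.7 ± 0.1 to 1.73 ± 0.551 (0.67, limma adjusted p = 0.014). Crystal adhesion and uptake genes had 8 of 18 higher and 1 lower (8 and 4 adjusted over the list alone, median 0.08, camera adjusted p = 0.201). CD44, the hyaluronan receptor, rose from 128 ± 20.3 to 300 ± 13.5 (1.24, SE 0.15, limma adjusted p = 8.41e-05) and the hyaluronan synthase HAS3 by 0.62, while osteopontin SPP1 was 2707 ± 412 and 2111 ± 296 (-0.36, limma adjusted p = 0.0819), a value that was 0.51 after quantile normalization. Ion transport genes had 12 of 23 higher and 4 lower, the same numbers adjusted over the list alone (median 0.29, camera adjusted p = 0.0328, adjusted p = 0.276 with an estimated correlation), with the phosphate transporter SLC20A1 (1.43) and the calcium pump ATP2B1 (1.55) higher and the vitamin D hydroxylase CYP24A1 (-2.26) lower.

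The lysosome list had 21 of 37 lower and 2 higher at 240 ug/ml (22 and 2 adjusted over the list alone) and a median of -0.32, or 0.10 with equal totals (camera adjusted p = 2.95e-04, adjusted p = 0.446 with an estimated correlation). NPC2, which carries cholesterol out of lysosomes, fell from 919 ± 45.3 to 290 ± 76.8, while the proton pump subunit ATP6V0D2 rose by 1.77. Cholesterol synthesis had 10 of 25 lower and 1 higher, the same numbers adjusted over the list alone, and a median of -0.24, or 0.16 with equal totals (camera adjusted p = 0.0175, adjusted p = 0.498 with an estimated correlation), with TM7SF2 (-1.57) lower. Autophagy genes had 9 of 26 lower and 4 higher (10 and 4 adjusted over the list alone, median -0.15, or 0.25 with equal totals, camera adjusted p = 0.0923), and cilium genes 9 of 31 lower and 6 higher, the same numbers adjusted over the list alone (median -0.10, or 0.32 with equal totals, camera adjusted p = 0.662). Fatty acid genes had 8 of 25 higher and 6 lower (9 and 6 adjusted over the list alone, median -0.06, or 0.37 with equal totals, mean 0.03, tested upward, camera adjusted p = 0.743), with fatty acid synthase FASN higher (1.08) and HADHB of beta oxidation lower (-0.67). Targets of the aryl hydrocarbon receptor had 1 of 9 higher and 4 lower, the same numbers adjusted over the list alone (median -0.23, or 0.19 with equal totals, camera adjusted p = 0.356), with CYP1B1 lower (-1.14).

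Markers of other cell types gave little to test. Leukocyte markers had 1 of 5 higher and 2 lower (2 and 2 adjusted over the list alone, median 0.34, mean -0.03, tested upward, camera adjusted p = 0.865), with CD74 lower (-1.33) and FCER1G higher (1.04). Fewer than 5 members were tested for fibroblasts and pericytes (4), endothelium (2), distal nephron (3) and podocytes (4), so these lists had no test.

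Comparing the highest with the lowest dose asked whether the response still changed above 60 ug/ml. TMEM158 (log2 fold change 1.53, SE 0.24, limma adjusted p = 0.00278), ARHGAP22, which acts on Rac (1.48), ANGPTL4 (1.43), VEGFA (1.30) and the antisense gene HMGA2-AS1 (1.40), whose reads cannot be told from those of an overlapping gene without the strand setting, were higher at 240 than at 60 ug/ml. MMP7 (-2.46, SE 0.33, limma adjusted p = 0.00159), IFITM1 (-2.37), the phosphate transporter SLC34A2 (-2.30), PDZK1IP1 (-1.83) and the proteoglycan lumican LUM (-1.82) were lower.

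In total 1964 genes were higher and 2204 lower at 240 than at 60 ug/ml, 65 and 162 of them by a log2 fold change of 1 or more. With equal library totals the split was 3934 higher and 913 lower, the median moving up by 0.19. These fold changes correlated with GC content across genes (r = -0.51) and with transcript length (r = 0.36), and 51.7% of the calls kept their direction and their side of the threshold with each library's GC trend subtracted. The counts also rested on single libraries. Leaving out 1 of the libraries at 60 ug/ml gave 922 higher and 1158 lower (the first) or 911 and 1145 (the second), and leaving out 1 at 240 ug/ml gave 1250 and 1436 (the second) or 1112 and 1383 (the third). Without the third library at 60 ug/ml they were 2412 and 2591.

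The 3 doses moved genes in like directions. Of the 7244 genes called at 240 ug/ml, 2345 were higher there with fitted fold changes that increased from 60 to 120 to 240 ug/ml. Another 2702 were lower there with fold changes that decreased in that order. The sign at 60 ug/ml was not required to match, and choosing genes by their call at 240 ug/ml favours this order. In all, 1126 genes were higher and 1331 lower at all 3 doses. Fold changes correlated across genes with r = 0.79 between 60 and 120, 0.72 between 60 and 240 and 0.90 between 120 and 240 ug/ml, against 0.50 in 100 simulations of unchanged groups sharing the same controls. Without the third library at 60 ug/ml the first and second of these were 0.67 and 0.59. The covariance was 0.154, 0.157 and 0.272, against 0.0231, 0.0232 and 0.0232 simulated, a difference of 0.131, 0.134 and 0.249. Calls shared between 60 and 240 ug/ml numbered 1153 higher and 1356 lower, against 294 and 395 for independent lists and at most 1 shared call in 10 simulations. Between 120 and 240 ug/ml they numbered 2324 and 3083, against 526 and 817, and between 60 and 120 ug/ml 1280 and 1463, against 237 and 350. The simulations held no changed genes, so few calls arose in them to be shared. The simulated count therefore does not show the overlap that shared controls give when many genes are called. With 3 control libraries the controls could not be split into parts of 2 or more, so part of the excess may come from the shared controls.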

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

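The tests of GC and length trends and the counts of other splits in this part were chosen after the results they bear on had been seen. A difference between doses set apart CLDN2, the cation-pore claudin of the proximal tubule. Its fold change at 240 against 60 ug/ml was -1.24 (limma adjusted p = 0.00804), from 226 ± 59.9 to 93.7 ± 16.2, while no dose passed against control. For 9 genes the fold changes at 60 and 240 ug/ml were both called and had opposite signs, and the difference between the doses was called too. They fall outside the naming rule and are named after their values were seen. DDIT3, the stress factor CHOP, stood at -0.26 at 60 and 0.33 at 240 ug/ml, and so did NFIL3, NIN, RPAP2, UBLCP1 and ZNF667 in sign, RPAP2 with -0.44 and 0.39. LAD1, a basement membrane protein of epithelia, stood at 0.35 and -0.35, G6PC3 at 0.33 and -0.47, and KIAA0930 at 0.26 and -0.32. Scaled to equal totals, LAD1 (0.55 and 0.08) and KIAA0930 (0.46 and 0.10) were positive at both doses, and the other 7 kept opposite signs. Most of these were close to 0 at 1 dose, NFIL3 (-0.04), DDIT3 (-0.06), ZNF667 (-0.08), UBLCP1 (-0.09) and NIN (-0.10) at 60 and G6PC3 (-0.05) at 240 ug/ml. Fold changes at 240 against 60 ug/ml went with GC content across genes (r = -0.51). Whether the 9 genes keep opposite signs with the GC trend subtracted was not examined.

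A signal also appeared in values that no gene comparison used. Of 6788 transcripts without a match in the annotation and with enough signal to test, 624 were higher and 638 lower at 240 ug/ml than in control, against 5956 and 6505 of all 61128 transcripts, so the share was no higher than among all. Their genes were not assigned here.

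The genes differing between 60 and 240 ug/ml (4168 calls) went with the GC content of their transcripts (r = -0.51). Subtracting each library's GC trend kept 51.7% of the calls and subtracting its length trend kept 78.7%, so neither trend alone accounts for all of them, by a bound of 50% set after the values were seen, and 49.3% were kept with both trends subtracted. For the 2015 calls that ended with the GC trend subtracted (48.3%), the median size of the fold change went from 0.42 to 0.23. This is a ratio of 0.543, while the median SE went from 0.11 to 0.10. These genes were chosen because their calls ended, and the SE did not widen, so a smaller fold change was largely set by that choice. The ratio therefore does not test the GC trend as their cause. Whether the trend itself came from library preparation or from the cells stays open. Its r differed between groups and also within them, from 0.201 to 0.702 at 60 and from -0.419 to -0.198 at 240 ug/ml, and library number 3 had the lowest r in each of the 4 groups.

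With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 4 comparisons 1 of 10 splits, the real one, gave as many calls, with 3177 at 60, 6155 at 120, 7244 at 240 and 4168 for 240 against 60 ug/ml, and at most 1 in any other split. For a difference between any of the 4 groups, 1 of 100 splits, the real one with 7173, gave as many calls, a share under 0.05. This share takes the 12 libraries as independent. It does not exclude a chance difference between cultures if the libraries of a group came from the same culture. The highest other split, which kept 10 of the 12 libraries with their own group, gave 7092 and the median split 1. The count therefore hardly tells the real grouping from that one. The 5 of the 99 random splits with the most calls all kept the 3 control libraries together, which points to a structure of the samples, the distance of the controls from the DHA libraries.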

How the results depend on the processing

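Quantile normalization, trend subtraction, protein-coding genes alone and transcripts in place of genes were chosen after the data had been seen. Of the values of named genes recomputed under all alternatives, 16941 stayed on their side of the threshold, 482 lost the threshold, 232 passed it and 13, called before or after, reversed. Among the 16941, 126 changed sign without a call on either side, as FN1 at 240 ug/ml did with equal totals. Of the list tests 2675 stayed on their side, 92 of them with the direction turned and no call on either side, 100 lost the threshold and 105 passed it.

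With equal library totals the genes higher and lower numbered 2782 and 657 at 60, 6090 and 1378 at 120, 7205 and 1531 at 240, and 3934 and 913 for 240 against 60 ug/ml, because all fold changes moved up. For the same reason NDUFS7 (0.2386) and VIM (0.3181) at 120, CDH2 (0.3236) and CDKN1A (0.1571) at 240, and APRT at 120 (0.3355) and 240 ug/ml (0.3026) reversed. With quantile normalization RPL3 (0.0276), CCN1 (0.2908) and VIM (0.7009) at 120, FN1 at 240 (0.3844) and SPP1 at 60, 120 and 240 ug/ml (0.3962, 0.4638, 0.5098) reversed, and the cause was not tested.

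At an adjusted p under 0.01 the counts were 679 higher and 641 lower at 60, 1553 and 2217 at 120, 2165 higher at 240, 645 and 890 for 240 against 60 ug/ml, and 4239 for any difference. With a log2 fold change of at least 1 they were 84 and 138, 237 and 659, 352 and 871, and 65 and 162 in the same order. Stricter calling lowers counts by construction. A fit on only the 2 groups compared gave 958 higher and 1106 lower for 240 against 60 ug/ml, with fewer libraries to estimate the spread. With the GC trend subtracted 1363 were lower at 240 than at 60 ug/ml, and 1375 with both trends subtracted. Among 61128 transcripts, 1068 were lower at 60, 4130 higher at 120, and 5956 higher and 6505 lower at 240 ug/ml. The cause was not tested.

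Camera called 12, 17 and 18 lists at 60, 120 and 240 ug/ml. With an estimated correlation it called 0, 0 and 0, and 6, 5 and 4 had an unadjusted p under 0.05. Fry, which asks another question, called 27 at 120 and 28 at 240 ug/ml.

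The correlations of fold changes (60 with 120, 60 with 240 and 120 with 240 ug/ml) were 0.6854, 0.651 and 0.8217 with a pseudocount of 0.1. With a pseudocount of 5 those of 60 with 120 and of 120 with 240 ug/ml were 0.8442 and 0.944. They were 0.8659, 0.7715 and 0.9591 with at least 10 in every library of a group, with fewer genes. That of 60 with 240 ug/ml was 0.7791 with the GC trend and 0.7682 with both trends subtracted, and that of 120 with 240 ug/ml was 0.9172 for genes with a mean of at least 1.

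Without each library in turn, the counts ranged from 920 to 1558 higher and 968 to 1877 lower at 60, 2026 to 2822 and 2709 to 3616 at 120, 2689 to 3421 and 3160 to 4025 at 240, 911 to 2412 and 1145 to 2591 for 240 against 60 ug/ml, and 5529 to 7745 for any difference. Those at 60 ug/ml moved by over 1.5 times without control replicate 1 (920 and 968), control replicate 2 (1071 lower) or replicate 1 at 60 ug/ml (922 and 1013). Those for 240 against 60 ug/ml did so without replicate 1 (922 and 1158) or 2 (911 and 1145) at 60 and replicate 2 (1250 and 1436) or 3 (1112 and 1383) at 240 ug/ml. Lists called ranged from 9 to 14, 15 to 18 and 17 to 20. The correlations ranged from 0.6688 to 0.8073, 0.5867 to 0.7458 and 0.8679 to 0.9113.

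A replicate block gave 1846 and 2137 calls at 60, 3028 and 3898 at 120, 3626 and 4275 at 240, 2434 and 2700 for 240 against 60 ug/ml and 8257 for any difference. Of the list tests, 109 stayed on their side of the threshold with the block and 2 lost it. No source used here says that replicate numbers pair libraries. With group means removed, the 18 same-numbered pairs correlated with r from -0.025 to 0.236 (median 0.057, against -0.035 for other pairs), 6 of them over 0.1. Those of number 3 ran from 0.04 to 0.236, and 8 of 12 libraries correlated best with their own number, so a pairing is not ruled out. Alternatives that need counts were not run, and without counts the depth of the libraries sets no stated limit.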

Other observations

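The lists of this part and the genes named from them were chosen after their values were seen, as were the tests on length and GC trends, scaling, matched mRNA and the acute serum response. The counts and camera p-values of these lists are therefore no independent test. The test on long 5' TOP messages was written before their median was computed. Genes of ribosome biogenesis, which act in the nucleolus to build ribosomes, rose at 240 ug/ml in 26 of 30 cases, with a median of 0.78 (camera adjusted p = 9.67e-13, adjusted p = 0.128 with an estimated correlation). Among them NOP2, an rRNA methyltransferase, rose by 1.17, the helicase DDX21 by 1.24 and POLR1A, the large subunit of RNA polymerase I, by 0.98. Amino acid transporters rose in 9 of 12 cases and fell in 1 (median 0.99, camera adjusted p = 1.01e-05, adjusted p = 0.128 with an estimated correlation), including the glycine transporter SLC6A9 (1.90), SLC3A2 (1.34), the partner of SLC7A5, and the cystine transporter SLC7A11 (1.29).

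Targets and feedback regulators of ERK signalling rose at 240 ug/ml in 11 of 11 cases (median 1.67, camera adjusted p = 6.68e-12, adjusted p = 0.109 with an estimated correlation). These genes were picked because they rose, so the count and the camera p-values were set by that choice and are no test. Of them 10 also belong to the immediate early list, and the remaining one, CCND1, is a named gene of each dose. The count is therefore not independent of that list either. The pregnancy-specific glycoproteins, secreted relatives of the CEA family, fell in 6 of 6 cases (median -1.67, camera adjusted p = 1.35e-04, adjusted p = 0.128 with an estimated correlation), with PSG5 at -2.59 and PSG8 at -2.27, though their near-identical sequences leave the single members uncertain. Messages with a 5' TOP, translated under mTOR control, other than ribosomal proteins fell in 19 of 30 cases and rose in 4 (median -0.60, or -0.17 with equal totals, camera adjusted p = 0.00161, adjusted p = 0.375 with an estimated correlation).

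Ribosomal protein mRNA was lower at 240 ug/ml by a median of -1.12. With the length trend subtracted the median was -0.92, and 47 of 48 still fell. That trend was fitted over all tested genes of any level. The shortest decile of protein-coding genes with a mean of at least 5 had a median of -0.55 before subtraction. The fit may therefore remove too little from short, abundant mRNA, and whether length accounts for the fall stays open. The tables argue against the scaling as the whole cause of the fall. Its median was -0.69 with equal totals and -0.40 after quantile normalization, where 27 fell and 2 rose. A fall shared by short, abundant mRNA of any function may account for most of it, since 10000 lists matched on length and level had a median of -0.924, and 0.73% of them lay at or below the ribosomal proteins. A fall of 5' TOP messages as a class stays open, since the 13 long ones had a median of -0.0795 (bootstrap interval -0.65 to 0.31), with 5 lower and 4 higher. With equal totals their median was 0.35, where that of all genes was 0.33.

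Immediate early genes were higher at 240 ug/ml by a median of 1.01, and by 1.11 with length and GC trends subtracted, which argues against those trends as the cause. An acute response to serum or handling at harvest could raise such genes, and it stays open. Genes of the acute serum response, all 10 of them from the immediate early list, had a median of 0.963, with 7 of 10 higher and 1 lower (camera adjusted p = 0.00161, adjusted p = 0.128 with an estimated correlation), and the comparison used for this test was changed once after its first value was seen. NR4A1 (1.72) and FOSB (1.62) rose, JUNB (-0.67) fell, and EGR1 stood at -0.54 (limma adjusted p = 0.0866). No other biological explanation was tested.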
